A study of Mus musculus with 4 samples.

How the data were processed

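The data are single-cell RNA profiles of cells sorted from mice with experimental autoimmune encephalomyelitis (EAE), a model in which autoreactive T cells inflame the CNS. Per the labels' protocols, tissue was digested with collagenase IV and DNase I and cells were sorted. There were 4 libraries, 1 for each combination of 2 tissues (CNS and a tissue labelled dLN) and 2 genotypes, a wild-type control and mice with floxed Bat3 alleles and CD11c-Cre, called Bat3cKO here. Bat3 is an older name of Bag6. Sample titles call the cells T cells, while the source and cell type labels of the same samples call them classical dendritic cells. The series' own description speaks of replicated bone-marrow-derived dendritic cell profiles from bulk sequencing, which is a different kind of data from these files. Groups were taken from the sample titles, and the genes in the cells were used to see which cell types the libraries held. How many animals each library came from is not given in the sources used here.

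The deposited files hold UMI counts (unique molecular identifiers, 1 per captured RNA molecule) per gene and cell barcode, whole numbers with no normalization, for 27998 genes. Per the submitters' processing notes, the authors used Cell Ranger 2.0 and the mm10 genome. The annotation release behind the gene models is not given in the sources used here. Gene places were taken from GENCODE mouse release 21 (GRCm38) by gene identifier, which matched 98.7% of the genes.

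Cells with under 200 genes or over 10% mitochondrial UMIs were left out. Doublets were scored within each library with the Scrublet method as implemented in scanpy, and those with the highest scores were removed, at a rate of 0.8% of a library's barcodes for every 1000 barcodes in it, which took 225 and 32 barcodes from the CNS control and Bat3cKO libraries and 192 and 117 from the dLN control and Bat3cKO libraries. Counts were scaled to 10000 UMIs per cell and log-transformed. Clustering used 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 over all libraries together, without TCR and immunoglobulin segments, mitochondrial, ribosomal protein and sex-linked genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3 were used, and edgeR 4.0.16 only for its TMM scaling factors.

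A cluster counted as T-lineage when its T cell markers were detected in at least 50% of its cells on average. A class name needed at least 3 of that class's markers among the cluster's top 30 genes by fold, or at least 2 among its top 10, and at least 3 markers seen in at least 15% of its cells. The markers were fixed before the data were examined, and this scoring rule was settled after the markers' values had been seen. Clusters that met no class stayed unnamed, and so did T-lineage clusters whose leading class was a non-T one. The latter holds for a cluster led by Klre1, with the NK cell or ILC1 markers Klre1, Klrk1 and Gzma among its top genes. The rule thus kept it out of the CD8 T-like class, and its share is given per library. Cells of the cycling and interferon-responding clusters were kept in all sums. The genes that define these clusters differ between the libraries, so their shares are not a separate result from the ratios of those genes.

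UMIs were summed over the T-lineage cells of each library and divided by their total to give CPM, that is, counts scaled to a common library total. With 1 library per group there is no spread between replicates, so no test was run and no p-value is given. Differences are log2 ratios of CPM with the exact conditional binomial 95% interval of a ratio of Poisson counts. Single CPM values have exact Poisson intervals and shares of cells have exact Clopper-Pearson intervals. All intervals cover counting error only. There was no replicate to leave out. A value of 0 is given with the limit that 3 counts allow. In list medians, a count of 0 in 1 library was replaced by 3 counts.

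Before the data were examined, 19 gene lists were fixed: Treg, Th17, Th1, encephalitogenic cytokine, coinhibitory and Tr1, naive and recirculating, Tfh, cytotoxic and CD8, TCR-induced immediate early, dissociation and heat shock, type I interferon response, cell cycle, glycolysis, oxidative phosphorylation, unfolded protein response, tissue homing and effector memory, TGF-beta and tissue residence, apoptosis and survival, and Th2. A member counted as higher or lower when its CPM differed by 1.5-fold or more with an interval that left out equality, and members under 10 CPM in both libraries were not measured. A list's median log2 ratio has an interval from 1000 Poisson redraws of the counts, and its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, describes these libraries only. Some genes stand in more than 1 list, such as Gzmb and Tnfrsf9.

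The rule for named genes was also fixed beforehand. It takes the 10 highest and 10 lowest log2 ratios per comparison among genes with at least 50 CPM in the higher library and at least 100 UMIs in both together, whose interval leaves out 0 and whose direction is the same when every cell has equal weight. TCR and immunoglobulin segments, mitochondrial, ribosomal protein, haemoglobin and sex-linked genes and numbered gene models were left out of that rule. In T-lineage cells of the CNS control, CNS Bat3cKO, dLN control and dLN Bat3cKO libraries, ribosomal protein genes held 30.5, 32.4, 44.8 and 42.6% of UMIs, mitochondrial genes 2.19, 2.23, 2.90 and 2.65%, and gene models 1.47, 2.09, 1.63 and 1.65%. Haemoglobin genes stood at 628, 687, 0.160 and 0.386 CPM, sex-linked genes at 193, 182, 204 and 151 CPM, and the TCR and immunoglobulin segments at 53.7, 57.8, 29.5 and 33.2 CPM. Some genes that the rule took are not reported here. Within classes the rule took 5 genes per direction with at least 100 CPM, where both libraries held at least 50 cells of the class. Only the Treg-like, effector-like and naive-like classes had been fixed for this. Ratios within CD8 T-like cells were computed as well and left out, because that class was not among them.

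To compare shares of cells with a UMI of a marker, every cell was thinned to 1500 UMIs, and 1273 shallower cells were left out. Shares without thinning, and shares with at least 2 UMIs without thinning, were the alternatives. How many cells carried Ccl1, Il17a and Il22 was counted after their values had been seen. The steps were tested on simulated counts before use. In the CNS pair (2332 genes), all 97 genes changed 2-fold and all 103 changed 4-fold were recovered, and the intervals covered 95.1% of the unchanged genes. In the dLN pair (1916 genes), all 99 and 101 such genes were recovered, with 95.4% coverage.

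The alternatives tried were other cell filters, no doublet removal, other resolutions and component numbers, clustering each tissue on its own, TMM and median-of-ratios scaling, a total without ribosomal and mitochondrial genes, equal weight per cell, thinned cells, all cells, a Cd3-positive gate, other limits on low genes, and, as the same cluster mix, both libraries of a tissue weighted to the mean of their cluster shares over clusters with at least 20 cells in each. The alternatives chosen after seeing the data were leaving out the naive-type and Klre1 clusters, and taking the ratios within Treg-like, CNS Th17-like and dLN naive T-like cells in each part of the class (single clusters of resolution 2 for CNS Th17-like, of resolution 1 for dLN naive T-like and of both for Treg-like cells). A comparison across single clusters was also set up after a first look at the data: it used the 14 pairs of clusters with at least 50 cells in both libraries of a tissue, without the cycling cluster, and the 3691 genes with at least 10 UMIs in every pair, with 0.5 UMIs added to each sum. Heat shock protein and chaperonin families were taken by gene symbol (Hsp, Dnaja, Dnajb, Dnajc, Cct and Tcp1), and median UMIs per cell were compared in each pair by redrawing cells, both also after seeing the data.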

Results

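Single cells were profiled from the CNS and from the tissue labelled dLN of mice with EAE, in a wild-type control and in Bat3cKO mice, in which CD11c-Cre acts on floxed Bat3 (Bag6). CD11c-Cre is active mainly in dendritic cells, so the comparison asks how T cells of each tissue differ when the deletion is aimed at another cell type. Each of the 4 groups was 1 library. The CNS control library held 5301 barcodes and 15265064 UMIs, the CNS Bat3cKO library 1986 barcodes and 5509331 UMIs, the dLN control library 4901 barcodes and 13151781 UMIs, and the dLN Bat3cKO library 3832 barcodes and 10811192 UMIs. Median UMIs per barcode were close, at 2378, 2411, 2377 and 2257.5 in the same order, with 1028, 1012, 838 and 817 genes. After filtering, 5040, 1924, 4705 and 3707 T-lineage cells remained, against 33, 24, 2 and 7 other cells, so the libraries held T cells rather than the dendritic cells that one of the labels names. There is no replicate check for any difference reported here, and all intervals are 95% intervals of counting error only.

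The targeted gene, Bag6 (ENSMUSG00000024392), lies on chromosome 17 from 35135178 to 35147322 (GRCm38, plus strand) and encodes a chaperone that guides newly made membrane proteins. In T-lineage cells Bag6 stood at 41.7 CPM (38.3 to 45.2) in CNS control and 41.1 (35.8 to 47.0) in CNS Bat3cKO cells, and at 30.001 CPM (27.0 to 33.2) in dLN control and 23.1 (20.2 to 26.2) in dLN Bat3cKO cells. The dLN intervals did not overlap. Over single clusters the Bag6 log2 ratio, Bat3cKO over control, ran from −1.60 to −0.04 in dLN and from −1.29 to 0.80 in the CNS. T cells are not the main cells that Cre targets. The non-T cells held only 8, 7, 1 and 0 Bag6 UMIs, and the sequenced tag can lie outside the deleted part. These values therefore check neither the deletion nor the labels. Xist had 0, 0, 1 and 0 UMIs, while Y-linked genes were found in all 4 libraries, with Ddx3y at 85.6, 91.0, 97.6 and 75.6 CPM. The Y-linked gene Eif2s3y was lower in Bat3cKO in both tissues, at 56.7 (50.4 to 63.5) against 79.8 CPM (75.2 to 84.6) in the CNS and 49.3 (45.1 to 53.8) against 70.4 (65.8 to 75.2) in dLN.

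T cells of the CNS differed in their make-up between the genotypes. Th17-like cells, named from Tmem176a, Tmem176b and Il17re, made up 43.1% (41.8 to 44.5) of T-lineage cells in the control and 16.7% (15.04 to 18.4) in the Bat3cKO library. Treg-like cells, named from Foxp3, Il2ra, Ikzf2 and other regulatory T cell genes, made up 24.6% (23.5 to 25.9) and 11.6% (10.2 to 13.1). Naive T-like cells, named from Ccr7, Lef1, Igfbp4 and other genes of resting T cells, made up 1.33% (1.03 to 1.69) of the control and 12.8% (11.4 to 14.4) of the Bat3cKO cells. CD8 T-like cells made up 9.35% (8.56 to 10.2) and 28.4% (26.4 to 30.5). In percentage points, Bat3cKO minus control, the differences were −26.5 (−28.6 to −24.2) for Th17-like, −13.1 (−14.9 to −11.1) for Treg-like, 11.5 (10.003 to 13.1) for naive T-like and 19.03 (16.9 to 21.3) for CD8 T-like cells.

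Both main parts of the CD8 T-like class of the CNS were larger in Bat3cKO: the cluster led by the granzyme gene Gzmk held 7.36% of control and 16.2% of Bat3cKO cells, and a cluster led by Ccr9 and Dapl1 held 1.88 and 11.5%. A cluster led by the NK receptor gene Klre1 stayed unnamed, with 0.258% of CNS control and 6.50% of CNS Bat3cKO cells. Cd8a was seen in 84.8% and Cd8b1 in 78.3% of its cells, and the NK cell marker Ncr1 in 0.725%, so they were mostly CD8 T cells. The CD8 T-like shares leave this cluster out. At resolution 1 it was absent from both dLN libraries, which allows a share of up to 0.0638% in the control and 0.0809% in Bat3cKO. At resolution 2 the cluster led by Gzma and Klre1 held 3 dLN control and 6 dLN Bat3cKO cells (0.162% of the latter), next to 0.655 and 6.65% of CNS control and CNS Bat3cKO cells. With 125 of its 138 cells at resolution 1 from the CNS Bat3cKO library, its size may be a feature of that 1 library. Unnamed T cells together made up 15.4 and 24.9% of the CNS libraries, mostly a cluster led by Tbc1d4, Slamf6 and Cxcr3 with 14.98 and 18.1%. For each Treg-like cell there were 1.75 (1.63 to 1.88) Th17-like cells in the control and 1.44 (1.21 to 1.72) in Bat3cKO. This direction turned at resolution 2 (0.789 and 1.12) and with the CNS clustered on its own (0.596 and 1.005).

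The size of the Th17-like difference depended on how finely the cells were clustered. At resolution 2 it was −5.56 points and with the CNS clustered on its own −3.15 points, because part of these cells then took the name of Th1 and GM-CSF effector cells (24.3% of control and 4.002% of Bat3cKO cells at resolution 2). Th17-like and these effector cells together differed by −25.9 and −25.8 points. At resolution 2 the top 10 genes of the effector cluster held Cxcr6 and Bhlhe40 of that class's markers, and the Th17 marker Il17re. Ifng, Csf2 and Tbx21 were not among them, so the name does not show that these cells made GM-CSF or interferon gamma. With the CNS clustered on its own, the naive T-like difference was 22.4 points and the CD8 T-like one 8.63 points. Without the naive-type clusters (the naive T-like ones and the CD8 T-like ones with Ccr7 or Dapl1 among their leading genes) and the Klre1 cluster, an alternative chosen after seeing the data, the Treg-like share was 25.6 against 16.9% and the Th17-like share 44.7 against 24.4%.

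**Figure D1:**
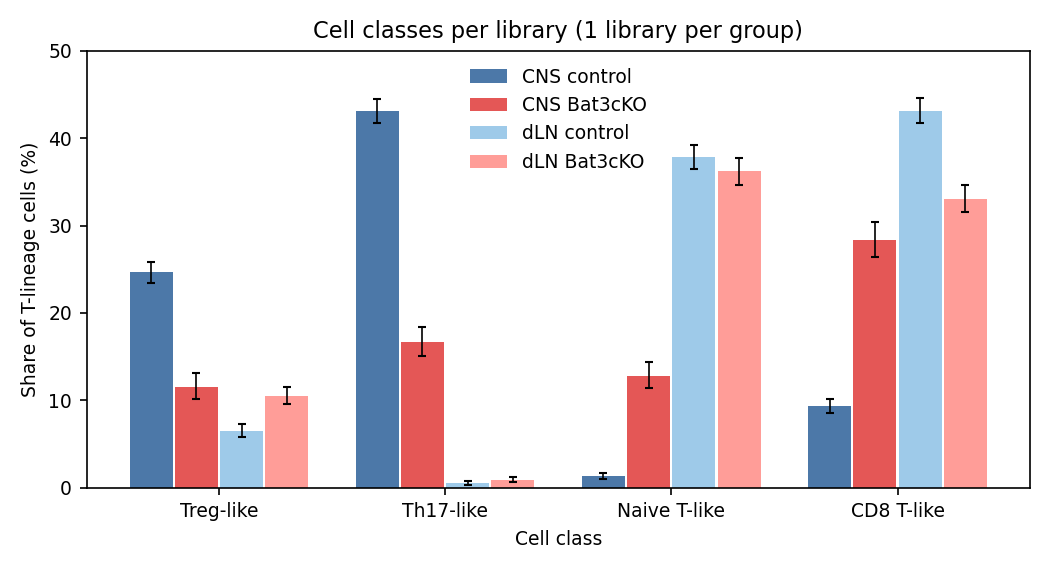
Share of T-lineage cells (%, vertical axis) in 4 cell classes for each of the 4 libraries, with exact 95% binomial intervals as error bars that cover counting error only. Th17-like cells stand at 43.1% of CNS control and 16.7% of CNS Bat3cKO cells, and CD8 T-like cells at 9.35 and 28.4%.

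The genes with the largest ratios over all CNS T cells included markers of these classes. Higher in Bat3cKO were the NK receptor gene Klre1 (chromosome 6, 129577905 to 129585827) at 56.1 against 3.53 CPM (log2 ratio 3.99, 3.55 to 4.46), and Gzma (chromosome 13, 113093825 to 113100981), which encodes a cytotoxic granule protease, at 679 against 52.0 CPM (3.71, 3.59 to 3.82). Cd8a, a chain of the CD8 coreceptor, was at 319 against 85.8 CPM (1.89, 1.79 to 2.001). Genes of resting T cells were higher too: Igfbp4 at 97.4 against 12.9 CPM (2.92), Dapl1 at 132 against 26.6 CPM (2.31), the lymph node homing receptor Ccr7 at 141 against 39.1 CPM (1.85), and Actn1 (2.12). Pik3ip1, an inhibitor of PI3-kinase, had a log2 ratio of 1.93, and Tsc22d3 (GILZ), a glucocorticoid-induced gene, was at 477 against 126 CPM (1.92). Ttr, which encodes the transthyretin that the choroid plexus secretes, was at 57.2 against 4.82 CPM (3.57). Ttr had a UMI in 14.2% (12.7 to 15.8) of all CNS Bat3cKO T cells, with 9.43 to 20.4% in each of 9 clusters, against 1.33% in the control, and it stood at 88453 CPM in the non-T cells of the Bat3cKO and 6642 CPM in those of the control library. Free RNA from other cells was not removed, so the Ttr ratio is not read as expression by T cells.

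Lower in CNS Bat3cKO T cells was first Ccl1 (chromosome 11, 82176657 to 82305690), a chemokine gene of activated T cells, at 2.84 against 89.6 CPM (−4.98, −5.82 to −4.25). Few cells carried Ccl1: 76 control cells, of which the 5 deepest held 61.2% of its UMIs, and 3 Bat3cKO cells. AA467197, at 33.0 against 140 CPM (−2.09), the transcription factor gene Irf8 (−1.81), the interferon-induced membrane protein genes Ifitm3 (41.3 against 140 CPM, −1.76) and Ifitm2 (−1.59), and the cytokine gene Lta (−1.70) were also lower. So were Ybx3 (−1.68), the costimulatory receptor gene Tnfrsf9 (116 against 368 CPM, −1.66), Lilr4b (−1.62), whose counts are hard to divide from its near-identical neighbour Lilrb4a, and the cell cycle inhibitor gene Cdkn1a (−1.54). When both CNS libraries were given the same cluster mix, which also leaves out clusters with under 20 cells in a library, among them the Klre1 cluster (13 control and 125 Bat3cKO cells), and so keeps 99.4% of control and 92.0% of Bat3cKO cells, most of these ratios shrank: Klre1 to 1.29, Gzma to 1.33, Igfbp4 to 0.43, Dapl1 to −0.02, Actn1 to 0.84, Pik3ip1 to 1.11, Cd8a to 0.31 and Ccr7 to 0.34. Among the lower genes, AA467197 moved to −1.20, Irf8 to −1.04, Ifitm3 to −0.84, Lta to −0.79, Tnfrsf9 to −0.68, Lilr4b to −0.83, Ifitm2 to −0.70 and Cdkn1a to −0.80. Ttr kept its ratio (3.61), which an equal mix leaves as it is for RNA spread over all clusters, whether or not T cells made it. Tsc22d3 moved to 1.30, Ccl1 to −3.71 and Ybx3 to −1.33. Without the naive-type and Klre1 clusters Igfbp4 was at 1.33, Pik3ip1 at 1.23 and Ccr7 at 1.09.

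**Figure D2:**
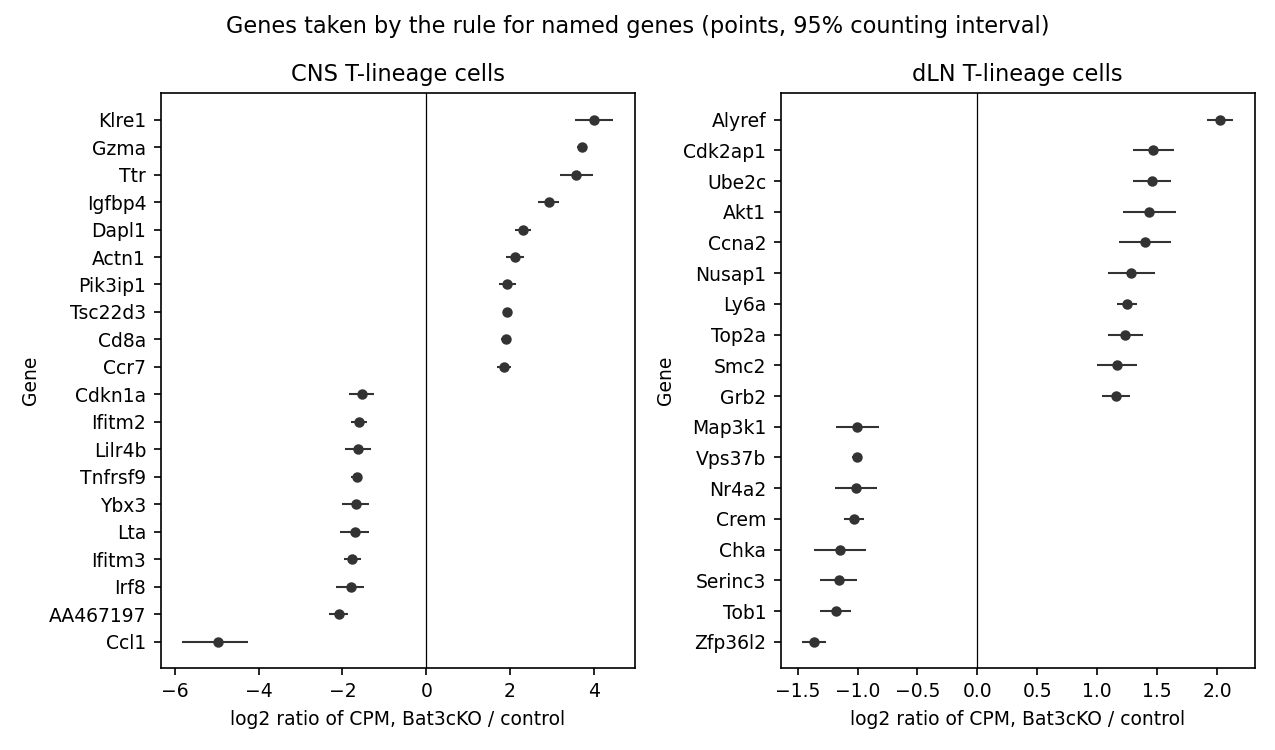
Log2 ratio of CPM, Bat3cKO over control (horizontal axis), of reported genes taken by the rule for named genes in CNS (left) and in dLN (right) T-lineage cells, as points with 95% counting intervals. In the CNS the ratios run from −4.98 for Ccl1 to 3.99 for Klre1, and in dLN from −1.36 for Zfp36l2 to 2.03 for Alyref.

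Among the lists of T cell programmes in the CNS, the Treg list was lower in Bat3cKO, with 11 of 15 measured genes lower, none higher, and a median of −0.87 (−1.005 to −0.79). Foxp3 (chromosome X, 7573644 to 7595245), the master regulator of Treg cells, was at 56.9 against 109 CPM (−0.94), with Il2ra at −1.32, Tnfrsf4 at −1.38 and Ikzf2 at −0.87. Of 11 Th17 genes, 5 were lower and 0 higher (median −0.52, −0.67 to −0.46). Il17a (chromosome 1, 20730905 to 20734496), the signature cytokine gene of Th17 cells, was at 129 against 248 CPM (−0.95), and Il22 at −0.73, while Il17f had a ratio of 0.51. Few cells carried much of these counts: the 5 deepest held 56.2% of the Il22 UMIs in the control and 77.4% in Bat3cKO, and 46.6 and 51.3% of the Il17a UMIs. Without those cells Il22 stood at 10.2 against 33.0 CPM and Il17a at 62.6 against 132 CPM. Of 6 encephalitogenic cytokine genes 4 were lower (median −0.76), including Tnf (−1.25), Bhlhe40 (−1.03) and Tnfsf11 (−0.79). Csf2, which encodes GM-CSF, was too low to measure, at 1.14 against 8.35 CPM. The Th1 list went both ways, with Ccl5 (1.60), Ccl4 (1.18) and Tbx21 (0.73) higher, Il18r1 (−0.60) lower and Ifng at 0.09 (7 of 11 not past the size rule, median 0.09). The cytotoxic and CD8 list was higher in 9 of 11 genes (median 1.24, 1.18 to 1.30), among them Cd8b1 (1.75), Xcl1 (1.91) and Nkg7 (1.24). The naive and recirculating list was higher in 6 of 10 (median 0.87, 0.80 to 0.93), with Lef1 at 1.002 and Tcf7 at 0.73.

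The coinhibitory and Tr1 list had 2 genes higher (Cd160 1.501, Prdm1 0.64), 2 lower (Icos −0.89, Nt5e −0.65) and 6 neither, with a median of −0.09. Il10 (3.60 against 8.20 CPM) and Havcr2 (2.84 against 7.34 CPM), which encodes the checkpoint receptor TIM-3, were too low. Of 4 Th2 genes 2 were lower, Areg (−1.41) and Il1rl1 (−0.73), with a median of −0.65. Of 3 Tfh genes Slamf6 (0.66) was higher and 2 were neither (median 0.29). The percentile among random lists was 0 for the Treg, Th17 and encephalitogenic lists, 100 for the cytotoxic and naive lists, 0.11 for Th2, 98.0 for Tfh, 89.8 for Th1 and 22.5 for the coinhibitory list. With the same cluster mix the medians were −0.21 for Treg, −0.10 for encephalitogenic cytokine, 0.21 for cytotoxic and CD8 and 0.34 for naive genes, and the signs turned for Th17 (0.40), Th2 (0.18), Th1 (−0.22) and coinhibitory genes (0.26). Foxp3 was then at 0.01 and Il17a at 0.40. The mix was made equal over clusters of resolution 1 only. Inside the Th17-like class 56.3% of control but 24.0% of Bat3cKO cells were effector cells at resolution 2. The turned Th17 and Il17a values can therefore still come in part from mix. Without the naive-type and Klre1 clusters the medians were −0.54 for Treg, −0.13 for Th17, −0.48 for encephalitogenic cytokine, −0.22 for Th2, 0.28 for coinhibitory, 0.49 for Tfh and 0.50 for naive genes.

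Lists of cell state in the CNS were mostly lower in Bat3cKO. Glycolysis genes were lower in 7 of 16 (median −0.58, −0.61 to −0.54), including the lactate exporter gene Slc16a3 (−1.49), Hk2 (−1.11) and the glucose transporter gene Slc2a1 (−0.98). The type I interferon response was lower in 7 of 14 (median −0.58, −0.66 to −0.44), with Isg20 at −1.34, Isg15 at −0.999 and Ifit1 at −0.95. TCR-induced immediate early genes were lower in 5 of 10 (median −0.58), such as Egr1 (−0.91) and Nr4a1 (−0.78), and tissue homing genes in 4 of 15 (median −0.38), such as S100a6 (−0.82), S100a4 (−0.79) and Ccr2 (−0.65). Of 12 TGF-beta and tissue residence genes 5 were lower, with Skil at −1.05 and Rgs1 at −1.04, and Cd9 (0.62) was higher (median −0.40). In the dissociation and heat shock list 5 of 15 were lower (median −0.43), among them Dnajb1 (−0.75), Hspa1a (−0.70), which has a near-identical copy in Hspa1b, and Junb (−0.62). Cell cycle genes were higher in 3 of 16, Ccna2 (1.04), Ube2c (0.74) and Birc5 (0.60), with a median of 0.34. Oxidative phosphorylation genes were neither in all 17 (median −0.20), the unfolded protein response had 1 of 14 lower, Xbp1 (−0.72, median −0.08), and apoptosis and survival genes had Bcl2 (1.14) and Fas (0.67) higher and Bcl2l1 (−0.70) lower among 11 (median −0.04). The percentile was 0 for glycolysis, interferon, TCR-induced and homing genes, 0.01 for TGF-beta, 0.03 for dissociation, 100 for cell cycle, 8.76 for oxidative phosphorylation, 25.1 for the unfolded protein response and 38.3 for apoptosis genes. With the same cluster mix the medians moved towards 0, to −0.16 for glycolysis, −0.18 for interferon, −0.07 for TCR-induced, −0.03 for homing, −0.13 for TGF-beta, −0.10 for dissociation and −0.06 for oxidative phosphorylation genes, while the cell cycle list was at 0.28 and the unfolded protein response and apoptosis lists stood at 0.09 and 0.03. Without the naive-type and Klre1 clusters they were 0.72 for cell cycle, −0.37 for glycolysis, −0.26 for interferon, −0.34 for TCR-induced, −0.13 for homing and −0.16 for dissociation genes.

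**Figure D3:**
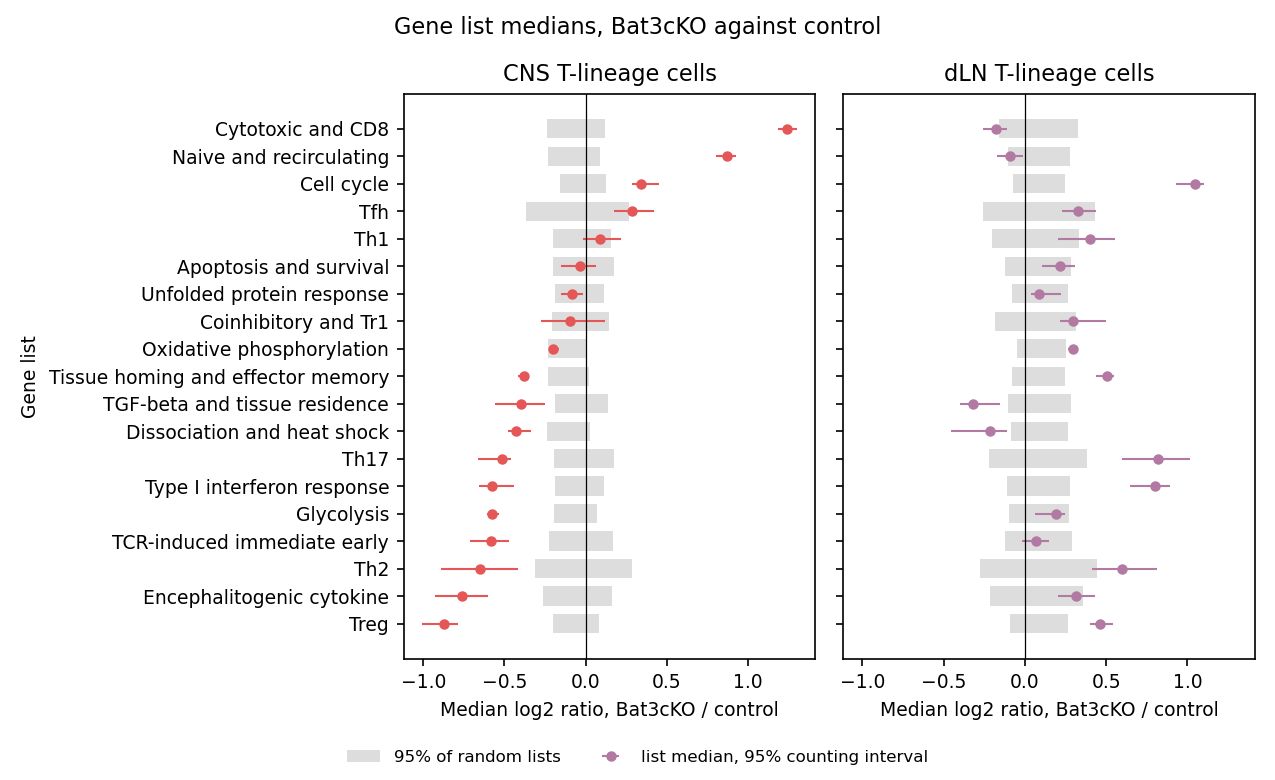
Median log2 ratio, Bat3cKO over control (horizontal axis), of 19 gene lists in CNS (left) and dLN (right) T-lineage cells, as points with 95% counting intervals, over grey bars that hold 95% of random lists matched on expression. The Treg list lies at −0.87 in the CNS and 0.46 in dLN, and the type I interferon list at −0.58 and 0.80.

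Inside CNS Treg-like cells (1242 control and 223 Bat3cKO cells), Foxp3 was at 368 CPM in Bat3cKO and 370.4 in control. Of 16 Treg genes 2 were lower, Ikzf4 (−0.99) and Tnfrsf9 (−0.80). Type I interferon genes were lower in 7 of 13 (median −0.71), with Ifit3 at −1.81, Usp18 at −1.35 and Ifit1 at −1.21. Il10, which encodes an anti-inflammatory cytokine, was at 13.2 against 28.9 CPM (−1.13, −2.30 to −0.15) and Lag3 at −0.68, while Prdm1 (0.94), Il27ra (0.75) and Pdcd1 (0.60) were higher. Naive and recirculating genes were higher in 7 of 10 (median 0.78), and so were Cd8a (1.58), Cd8b1 (0.90), Gzma (1.84) and Klrd1 (1.42), genes of CD8 T cells. Over all CNS T cells Gzma (679 against 52.0 CPM) and Cd8a (319 against 85.8 CPM) were higher in Bat3cKO too. CD8 T cells or their RNA within this class therefore cannot be told apart from expression by Treg-like cells. The leading genes were Zfp36l2 (1.81), Serinc3 (1.57), Tsc22d3 (1.53), the chaperone gene Hsph1 (1.17) and Wdr89 (1.05) on the higher side, and the fatty acid binding protein gene Fabp5 (−1.23), Ifit1, Rtp4 (−1.14), Ctla2a (−1.12) and Camk2n1 (−1.07) on the lower. The cluster in which most dLN Treg-like cells lay held 2.82% of the control and 10.3% of the Bat3cKO cells of this class. At resolution 2, in a split added after seeing the data, the Tnfrsf9-led cluster with most of these cells (1132 and 180) had naive genes higher in 5 of 10 (median 0.65), Zfp36l2 at 1.78, Serinc3 at 1.70, Il10 at −0.97 (−2.22 to 0.07) and Pdcd1 at 0.37. Interferon genes were lower in 1 of 12 there (median −0.26), with Ifit1 at −0.16, so the interferon difference was smaller in this cluster than over the class.

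Inside CNS Th17-like cells (2174 control and 321 Bat3cKO cells), Il17f (1.74), Ccr6 (1.21) and Tmem176a (0.65) were the Th17 genes higher in Bat3cKO, with none of 12 lower and a median of 0.43. The class held different parts in the 2 libraries, as a split added after seeing the data shows. Of its control cells 56.3% were named Th1 and GM-CSF effector cells at resolution 2, and of its Bat3cKO cells 24.0%, while the Tmem176a-led Th17 cluster of that resolution held 32.8 and 67.3%. In that Th17 cluster Il17f was at 2.20, Ccr6 at 0.46, Tmem176a at 0.29 and Il17a at 0.14 (−0.11 to 0.40), so part of the ratios of Ccr6, Tmem176a and Il17a over the class can come from its mix, as can part of those of genes below. Over the whole class Il17a was at 645 against 517 CPM (0.32, 0.19 to 0.44). The inflammatory cytokine genes Csf2 (−1.54, −3.02 to −0.37), Il2 (−1.13) and Ifng (−1.12) were lower over the class. By part they were lower only in the Th17 cluster led by Ccl1, with 201 control but 28 Bat3cKO cells (Il2 −2.85, Ifng −1.29, Csf2 at most −1.58 from 0 against 71 UMIs), and not, in the same order, in the Tmem176a-led cluster (0.07, 0.24 and 0.56) or the effector cells (1.41, 0.07 and 0.64). Among coinhibitory genes Prdm1 (1.20), Maf (0.89) and Il27ra (0.78) were higher. The leading genes were Il17f, Serinc3 (1.59), Lmo4 (1.42), Slamf6 (1.42) and Zfp36l2 (1.37) against Ccl1 (−3.84), Ctsw (−1.66), Plac8 (−1.64), the cytokine signalling inhibitor gene Socs3 (−1.28) and Alyref (−1.04). In the Tmem176a-led cluster and the effector cells Slamf6 was at 0.79 and 0.59, Lmo4 at 0.88 and 0.70 and Ctsw at −0.59 and −0.72, Plac8 was at 0.34 in the Ccl1-led cluster, and Il27ra at −0.43 in the effector cells (6 UMIs in Bat3cKO). Serinc3 (1.49, 1.68 and 1.62) and Zfp36l2 (1.34, 1.22 and 1.07) were higher in the Tmem176a-led cluster, the effector cells and the Ccl1-led cluster. In CNS naive T-like cells (67 control and 247 Bat3cKO cells) the leading genes were Zfp36l2 (2.38), the chaperone genes Stip1 (2.11) and Hspd1 (1.95), Dusp2 (1.75) and Lrrc58 (1.65), which rest on 7 to 9 control UMIs each (Zfp36l2 1.42 to 3.53, Stip1 1.09 to 3.35, Hspd1 0.86 to 3.30, Dusp2 0.71 to 2.99, Lrrc58 0.61 to 2.90), against Pitpna (−1.17), Gpx1 (−1.09), Jund (−0.87), Junb (−0.78) and Snrpd3 (−0.77). Of 6 cytotoxic and CD8 genes there, Cd8b1 alone was higher by the size rule (2.09, 0.46 to 4.42, from 3 control UMIs). Cd8a and Gzma had 8 UMIs each in Bat3cKO and 0 in control cells. Ctsw was at 1.09, Nkg7 at 0.35 and Klrd1 at −0.51. The list median of −0.08 puts 3 counts in place of each 0, so it does not speak against CD8 T cells. A larger part of CD8 T cells in the Bat3cKO cells of this class was not ruled out.

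Shares of T-lineage cells with at least 1 UMI of a marker, in cells thinned to 1500 UMIs, need no class names. The T-lineage cells, and the CD8 T-like cells set beside them, were still taken by cluster. Foxp3 was seen in 11.5% of CNS control and 5.81% of CNS Bat3cKO cells (16.9 and 8.32% without thinning), against 2.0 and 0.594% in CD8 T-like cells, which should lack it. Il17a was seen in 5.43 and 3.75% (7.18 and 4.47% without thinning), against 0.5 and 0.594% in CD8 T-like cells, and Csf2 in 0.814 and 0.176% (1.13 and 0.312% without thinning), against 0.250% and 0 of 505 cells (up to 0.594% allowed by 3 counts), so whether the Csf2 share of Bat3cKO cells lies above background stays open. Il10 was seen in 0.945 and 0.528% of cells (1.29 and 0.624% without thinning), against 0 of 400 cells (up to 0.750% allowed) and 0.198%. Havcr2, at 0.704 and 0.411% (1.55 and 0.780% without thinning), lay at the level in CD8 T-like cells (1.0 and 0.396%). These cells were not shown to lack Havcr2, so whether its shares lie above background stays open. Ifng, which CD8 T cells also make, was seen in 4.86 and 6.69% of cells (7.12 and 9.36% without thinning), and Mki67, a proliferation marker, in 1.87 and 2.23% (3.29 and 3.95% without thinning), against 1.0 and 0.594% in CD8 T-like cells. For Mki67 that class is no background, since the cycling cluster, with Cd8a in 22.4% of its cells, lies outside it. Median depths were 2446.5 and 2543 UMIs in T-lineage and 2373.5 and 2540 in CD8 T-like cells, and thinning left out 494 and 226 cells of these libraries. In non-T cells Foxp3 was seen in 0 of 31 and 1 of 17 cells.

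In dLN, Treg-like cells made up 6.55% (5.86 to 7.29) of control and 10.5% (9.58 to 11.6) of Bat3cKO T cells, a difference of 4.001 points (2.78 to 5.24). CD8 T-like cells made up 43.1 and 33.1%, a difference of −10.1 points (−12.2 to −7.98). Of this class, the cluster led by Cd8b1, Ccr7 and Vps37b was smaller in Bat3cKO, with 34.9% of control and 19.5% of Bat3cKO cells. The Ccr9-led cluster was larger, with 7.95 and 12.9%. The Gzmk-led cluster held 0.298% (0.163 to 0.499) and 0.593% (0.372 to 0.897). Naive T-like cells were at 37.8 and 36.2% (−1.63 points, −3.72 to 0.466) and Th17-like cells at 0.510 and 0.890% (0.380 points, 0.00861 to 0.782), and unnamed T cells at 9.54 and 12.8%. The cycling cluster held 2.34% of control and 5.42% of Bat3cKO cells (3.08 points, 2.23 to 3.97). The interferon-responding cluster held 0.0850 and 1.08% (0.994 points, 0.660 to 1.39). Most dLN Treg-like cells lay in another cluster than those of the CNS. All naive-type clusters together held 80.7% of control and 68.7% of Bat3cKO cells. Among the remaining cells, a setting chosen after seeing the data, the Treg-like share was 33.9% (30.8 to 37.1) and 33.7% (31.0 to 36.5), a difference of −0.206 points, which lies within counting error. The Th17-like share there was 2.64% (1.70 to 3.90) and 2.84% (1.96 to 3.97), from 24 and 33 cells, also within counting error. The naive T-like difference had the other sign at resolution 2 (0.740 points), and the Th17-like one was 0.900 points with dLN clustered on its own.

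In dLN T cells of Bat3cKO mice, genes of dividing cells were higher: Ube2c, which drives exit from mitosis, at 105 against 38.3 CPM (1.45, 1.30 to 1.61), cyclin A2 (Ccna2, 1.40), Nusap1 (1.28), topoisomerase Top2a (1.23) and the condensin gene Smc2 (1.16). The largest ratio was that of Alyref (chromosome 11, 120592121 to 120598365), an mRNA export factor gene, at 288 against 70.7 CPM (2.03, 1.92 to 2.14). Cdk2ap1 (1.47), the kinase gene Akt1 (1.44), the interferon-responsive surface protein gene Ly6a (341 against 143 CPM, 1.25) and the signalling adaptor gene Grb2 (1.16) were also higher. Lower were Zfp36l2 (chromosome 17, 84183931 to 84187947), an RNA-decay factor gene, at 110.3 against 284 CPM (−1.36, −1.46 to −1.27), the antiproliferative gene Tob1 (−1.18), Serinc3 (−1.16), Chka (−1.14), Crem (−1.03), Nr4a2 (−1.01), Vps37b (663 against 1329 CPM, −1.004) and Map3k1 (−1.003). With the same cluster mix, the mitotic genes Ube2c (0.31), Ccna2 (0.30), Nusap1 (0.08), Top2a (0.21) and Smc2 (0.49) lost most of their ratios and Vps37b moved to −0.51, while Alyref was at 1.58, Akt1 at 1.05, Grb2 at 0.996 and Ly6a at 0.86. Without the naive-type and Klre1 clusters Ube2c was at 0.81, Ccna2 at 0.72, Nusap1 at 0.61, Top2a at 0.61, Smc2 at 0.72, Ly6a at 0.73 and Grb2 at 0.75.

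The cell cycle list was higher in 13 of 16 genes (median 1.05, 0.93 to 1.10), such as Mki67 (1.18) and Cdk1 (1.13), with a same-mix median of −0.05. The type I interferon response was higher in 8 of 12 (median 0.80, 0.65 to 0.89), with Ifit1 at 1.74, Usp18 at 1.47 and Ifit3 at 1.19. The Th17 list was higher in 5 of 7 (median 0.82), among them Ccr6 (1.22) and Il22 (1.13). For Il22 the 5 deepest cells held 69.0% of the control and 42.4% of the Bat3cKO UMIs, and without them it stood at 27.0 against 6.66 CPM. Il17a was at 45.8 against 0.963 CPM (5.57), with 475 UMIs in 52 Bat3cKO cells, of which the 5 deepest held 64.4%, and 12 UMIs in 9 control cells. The Treg list was higher in 5 of 14 (median 0.46, 0.40 to 0.54), with Foxp3 at 31.0 against 19.9 CPM (0.64) and Il2ra at 0.68. Tissue homing genes were higher in 6 of 14 (median 0.50), such as Cd44 (0.75) and Lgals1 (0.72), Th2 genes in 2 of 3 (Areg 0.79, Ccr4 0.60, median 0.60), and Th1 genes in 2 of 6 (Cxcr3 0.88, Ccl5 0.60, median 0.40). The percentile was 100 for the cell cycle, interferon, Th17, Treg and homing lists, 99.4 for Th2 and 99.3 for Th1. With the same cluster mix the medians were 0.57 for interferon, 0.30 for Th17 and 0.16 for Th2 genes, and the signs turned for Treg (−0.02), homing (−0.05) and Th1 genes (−0.04), with Foxp3 at 0.01. Without the naive-type and Klre1 clusters the medians were −0.08 for Treg, 0.44 for Th17, 0.42 for cell cycle, 0.014 for homing, 0.10 for Th2 and −0.0039 for Th1 genes. With Foxp3 at −0.0083 there, its direction turned as well. Among Th17 genes of at least 50 CPM the median was 0.12.

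Of 8 coinhibitory and Tr1 genes in dLN 3 were higher, Maf (0.94), Gzmb (0.81) and Pdcd1 (0.77), with a median of 0.30, and of 5 Tfh genes Cxcr5 (1.06) and Tox2 (0.99) were higher (median 0.33). Cd40lg (0.60) was the higher one of 5 encephalitogenic cytokine genes (median 0.31). None of the 11 naive genes passed the size rule (median −0.09). In the cytotoxic and CD8 list 2 of 7 were higher, such as Gzma (1.19), and Klrd1 (−0.91) was lower (median −0.18). With each cell weighted equally that median was 0.00036, with the same cluster mix 0.07, and without a limit on low genes −0.06. Of 13 dissociation genes 4 were lower, Jun (−0.90), Fos (−0.71), Hspa1a (−0.68) and Ier2 (−0.65), with a median of −0.22. TCR-induced genes went both ways, with Irf4 (0.78) and Myc (0.66) higher and 2 of 10 lower, such as Nr4a2 (median 0.07). TGF-beta genes had Rgs1 (0.62) higher and Smad7 (−0.66) lower among 11 (median −0.32). The unfolded protein response had 3 of 13 higher, such as Sdf2l1 (1.001), and Dnajb9 (−0.79) lower (median 0.09). Slc2a1 (−0.67) was the lower one of 15 glycolysis genes (median 0.19), none of 17 oxidative phosphorylation genes passed the size rule (median 0.29), and of 10 apoptosis genes Bak1 (0.60) was higher and Bcl2l11 (−0.61) lower (median 0.22). The percentile was 96.6 for the coinhibitory, 92.0 for the Tfh, 94.9 for the encephalitogenic, 3.13 for the naive and 1.84 for the cytotoxic list. It was 0.03 for dissociation, 46.1 for TCR-induced, 0.01 for TGF-beta, 45.8 for unfolded protein response, 86.2 for glycolysis, 99.7 for oxidative phosphorylation and 91.5 for apoptosis genes. With the same cluster mix the encephalitogenic (−0.03), TCR-induced (−0.12) and glycolysis (−0.11) medians turned, the Tfh (0.10), oxidative phosphorylation (0.13), unfolded protein response (0.02), naive (−0.02), coinhibitory (0.24), TGF-beta (−0.23) and apoptosis (0.15) medians shrank, and the dissociation median was −0.30. Without the naive-type and Klre1 clusters the coinhibitory (−0.038), encephalitogenic (−0.12), TCR-induced (−0.076), glycolysis (−0.0024) and apoptosis (−0.099) medians turned.

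Within dLN Treg-like cells (308 control and 391 Bat3cKO cells), Foxp3 was at 166 against 154 CPM (0.11, −0.20 to 0.43), and 1 of 16 Treg genes, Lrrc32 (−0.75), was lower. The granzyme gene Gzmb (1.18), Alyref (2.01), Hsph1 (1.18), Ly6a (1.16) and Taf10 (1.08) led the higher side, and Zfp36l2 (−1.66), Dgat1 (−1.19), Serinc3 (−1.18), March7 (−0.98) and Tnfaip3 (−0.98) the lower. Of 7 cytotoxic and CD8 genes Gzmb alone was higher, and Klrd1 (−2.10) and Xcl1 (−1.68) were lower, with a median of −0.55. The class had different parts: the Tnfrsf9-led and Gzmb-rich cluster of the CNS Treg-like cells held 7.14% of its control and 13.8% of its Bat3cKO cells, and at resolution 2 the Cd83-led cluster held 76.0 and 57.3%. In that Cd83-led cluster, split off after seeing the data, Gzmb was at 1.41, Alyref at 1.88, Ly6a at 1.46 and Taf10 at 1.01, with Hsph1 at 0.38 (−0.32 to 1.07), Zfp36l2 at −1.38, Dgat1 at −0.74, Serinc3 at −0.95, March7 at −0.86 and Tnfaip3 at −0.52. Within dLN naive T-like cells (1780 control and 1342 Bat3cKO cells), interferon genes were higher in 8 of 11 (median 0.67), such as Usp18 (1.53), and dissociation genes lower in 6 of 13 (median −0.43), such as Hspa1a (−1.02). Alyref (1.56), Ly6a (1.11), Grb2 (1.11), Taf10 (1.05) and Ptpn6 (0.94) led the higher side, and Zfp36l2 (−1.48), Crem (−1.37), Tob1 (−1.23) and Tnfaip3 (−1.16) the lower. The Dusp10-led cluster held 79.7% of the control and 59.1% of the Bat3cKO cells of this class, and the Igfbp4-led cluster the rest. In these 2 clusters, split after seeing the data, Alyref was at 1.62 and 1.504, Ly6a at 1.05 and 0.87, Grb2 at 0.997 and 1.37, Taf10 at 1.02 and 1.17, Ptpn6 at 1.07 and 0.53, and Zfp36l2 at −1.67 and −0.90. Tob1 was at −1.01 and −0.54, Tnfaip3 at −0.84 and −0.83, Crem at −1.02 and 0.31 and Hspa1a at −0.06 and −2.24, with medians of 0.78 and 0.37 for interferon and −0.16 and −0.63 for dissociation genes. With 24 and 33 Th17-like cells, that class was not compared in dLN. Foxp3 was seen in 2.04% of dLN control and 3.43% of dLN Bat3cKO cells after thinning (3.42 and 5.58% before), against 0.359 and 0.0827% in CD8 T-like cells. Il17a was seen in 0.0702 and 0.892% (0.191 and 1.40% before), against 0 of 1950 cells (up to 0.154% allowed) and 0.0827%, and Mki67 in 0.866 and 2.12% (1.998 and 4.94% before), against 0.0513 and 0.0827%. For Mki67 the CD8 T-like cells are no background, since the cycling cluster lies outside their class.

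Between the tissues of control mice, CNS T cells carried effector genes and dLN T cells genes of resting cells. TMM factors would shift all ratios of this comparison by −0.31 on the log2 scale in control and by −0.30 in Bat3cKO mice, and the median of all genes was 0.37 and 0.29, so ratios are to be read against these. Il17a was at 248 against 0.963 CPM (8.01, 7.20 to 8.96), Ccl1 at 89.6 CPM against 3 UMIs in dLN (8.54, 6.99 to 10.82), the chemokine gene Ccl5 at 2039 against 76.1 CPM (4.74) and Ifng at 50.9 against 2.01 CPM (4.67). AA467197 (6.13), the inhibitory receptor genes Lilrb4a (5.19) and Lilr4b (4.53), Fgl2 (4.84), the leukotriene receptor gene Ltb4r1 (4.50) and Rgs16 (4.48) were also higher in the CNS. Higher in dLN were Tubb2a (−4.54), Ccr7 (39.1 against 757 CPM, −4.28), Igfbp4 (−4.05), Dapl1 (−3.53), Vps37b (−3.47), Dusp10 (−3.32), Frat2 (−2.91), Actn1 (−2.89), Itm2a (−2.63) and Tdrp (−2.59).

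All 11 Th17 genes (median 2.25), 9 of 11 Th1 genes (3.54), 13 of 15 Treg genes (1.89), all 15 homing genes (2.06), all 14 interferon genes (1.92) and 15 of 16 glycolysis genes (1.11) were higher in control CNS, and 9 of 11 naive genes were lower (−1.59). In the cytotoxic and CD8 list 6 of 10 were higher and 3 lower (median 1.09). Examples were Cxcr3 (4.09), Cxcr6 (3.43), Foxp3 (2.45), Ifit1 (3.47) and Hk2 (2.05). The dissociation list was higher in 10 of 15 (median 1.30), with Hspa1a at 2.82.

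In Bat3cKO mice the genes with the largest ratios of CNS to dLN included cytotoxic genes. Ccl5 was at 6169 against 115 CPM (5.74, 5.66 to 5.83), Gzma at 679 against 20.6 CPM (5.04), Klre1 at 56.1 against 0.676 CPM (6.38) and Ifng at 54.2 against 1.83 CPM (4.89). Fgl2 (5.03), Ccl4 (4.62), Camk2n1 (4.44), Gzmk (4.31) and the NK receptor gene Klrk1 (3.71) were higher too, and Ttr stood at 57.2 CPM against 0 UMIs in dLN, at least 198-fold higher against a floor of 3 counts. Higher in dLN were Tubb2a (−2.88), Vps37b (−2.42), Dusp10 (−2.34), Areg (−2.14), Ifngr2 (−2.02), Rel (−1.91), Ccr7 (−1.90), Tgif1 (−1.88), Alyref (−1.86) and Marcksl1 (−1.85). The list medians were 1.32 for Th17, 2.86 for Th1, 0.61 for Treg, 1.20 for homing, 0.55 for interferon, 0.60 for glycolysis, −0.58 for naive and 2.06 for cytotoxic and CD8 genes. The CNS ratio minus the dLN ratio of genotype ran over the 19 lists from −1.37 for interferon to 1.42 for cytotoxic and CD8 genes, with −1.33 for Treg, −1.33 for Th17, −0.04 for Tfh and −0.08 for TGF-beta genes. In the same order these were, with the same cluster mix in each tissue, −0.74, 0.14, −0.19, 0.10, 0.25 and 0.09, so most of the larger ones shrank. This difference between tissues was not tested, since each group is 1 library.

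A comparison across single clusters, set up after a first look at the data, covered 7 CNS and 7 dLN clusters and 3691 genes, of which 28 were higher and 8 lower in Bat3cKO cells of all 14. All clusters of a tissue share the same pair of libraries. A difference of a whole library can thus repeat in each of them, and the 14 are not replicates. Of the 39 genes whose symbols belong to heat shock protein and chaperonin families, grouped after seeing the data, 6 were higher in all 14 and 0 lower (15.4% higher, against 0.759% of all genes compared), and 27 of the 39 had a median above 0. Among all 3691 genes, which were not matched to these families on expression, 2125 had a median above 0. The genes Hsph1, Hsp90ab1, Fkbp4 and Ahsa1, chosen after their values were seen, were among the 28, with median log2 ratios of 1.20, 0.42, 0.85 and 0.76 over CNS clusters and 1.11, 0.52, 0.57 and 0.69 over dLN clusters. Rbm3, a cold-induced RNA-binding protein gene, was lower in 14 of 14 (medians −0.61 and −0.57). Others did not follow: Dnajb1 was below 0 in 13 of 14, Dnajb9 in 12, Hspa1a, the inducible heat shock protein gene, in 13, and its near-identical copy Hspa1b in 9 of 14, and the dissociation and heat shock list fixed beforehand had medians of −0.43 in the CNS and −0.22 in dLN over all T cells. H2-Q7 (0.59 and 0.44) and H2-Q6 (0.53 and 0.24) were higher in all 14. These class I genes lie close to Bag6 on chromosome 17, and their counts are hard to divide from those of near-identical paralogs.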

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

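The results below were picked out for differing in direction between the tissues or for lying outside the comparisons of T cells, and no difference between the tissues was tested, since each group is 1 library. All tests of explanations were chosen after the result was seen, except those of Cirbp and of depth per cell in thinned cells.

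Between CNS and dLN, the difference in share, Bat3cKO minus control, went in opposite directions for Treg-like cells (−13.1 and 4.001 points), Th17-like cells (−26.5 and 0.380 points) and CD8 T-like cells (19.03 and −10.1 points). The CD8 T-like class held other cells in each tissue. Its dLN fall lay in the cluster led by Ccr7 and Vps37b (34.9 and 19.5%), which held 0.0992 and 0.728% of the CNS libraries. The Ccr9-led cluster was larger in Bat3cKO in both tissues (1.88 and 11.5% in the CNS, 7.95 and 12.9% in dLN). The dLN Treg-like difference without the naive-type and Klre1 clusters, a setting chosen after seeing the data, was −0.206 points (33.9%, 30.8 to 37.1, and 33.7%, 31.0 to 36.5), no difference beyond counting error. The dLN Th17-like share in that setting, from 24 and 33 cells, was 2.64% (1.70 to 3.90) and 2.84% (1.96 to 3.97), also no difference beyond counting error. List medians went in opposite directions for Treg (−0.87 and 0.46), Th17 (−0.52 and 0.82), cytotoxic and CD8 (1.24 and −0.18), type I interferon (−0.58 and 0.80), tissue homing (−0.38 and 0.50) and Th2 genes (−0.65 and 0.60). Of these lists the interferon list alone kept opposite signs with the same cluster mix (−0.18 and 0.57), and the medians were −0.21 and −0.02 for Treg, 0.40 and 0.30 for Th17, 0.21 and 0.07 for cytotoxic and CD8, −0.03 and −0.05 for homing and 0.18 and 0.16 for Th2 genes. Among single genes, log2 ratios in CNS and dLN were −4.98 and 5.22 for Ccl1, −2.09 and 1.18 for AA467197, −1.76 and 0.99 for Ifitm3, −1.68 and 2.39 for Ybx3, and −1.59 and 0.99 for Ifitm2. Ccl1 and Il17a are carried by few cells, which was looked at after their values were seen: in dLN, 93 Ccl1 UMIs came from 4 Bat3cKO cells and 3 from 2 control cells. Alyref stood at −0.88 and 2.03, Cdk2ap1 at −0.62 and 1.47, Akt1 at −1.18 and 1.44, Ly6a at −0.85 and 1.25, and Grb2 at −0.71 and 1.16. The opposite order was seen for Zfp36l2 (1.58 and −1.36), Serinc3 (1.23 and −1.16) and Map3k1 (0.73 and −1.003).

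Outside the T cell genes, haemoglobin RNA in CNS T cells stood at 628 CPM in the control and 687 CPM in Bat3cKO. The few non-T cells of the CNS differed in kind: Ttr stood at 6642 CPM in control and 88453 CPM in Bat3cKO cells, and the macrophage gene Lyz2 at 20314 and 304 CPM.

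Naive-type T cells held 3.31% of CNS control and 25.1% of CNS Bat3cKO T cells. More blood with its erythrocyte RNA is argued against, since haemoglobin CPM differed 1.09-fold (1.05 to 1.14) and the share of naive-type cells 7.56-fold (6.33 to 9.07). Cells with Hbb-bs were also more frequent in Bat3cKO (8.21 against 2.40%), so some blood, or blood freed of erythrocytes, may still contribute. Carry-over from the dLN Bat3cKO library is argued against by the clusters led by Ccr7 and Vps37b or by Dusp10, which held 4.36% (2.72 to 6.58) of naive-type cells in CNS Bat3cKO and 59.6% (57.6 to 61.5) in dLN Bat3cKO, and a loss of Th17-like and Treg-like cells alone by the odds ratio of naive-type to Gzmk-high CD8 T-like cells, 3.44 (2.71 to 4.37). Handling of the single libraries and the genotype itself stay open, and neither was tested.

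Of 39 genes of heat shock protein and chaperonin families 6 were higher, and Rbm3 was lower, in Bat3cKO cells of each of the 14 clusters compared, while Dnajb1 was below 0 in 13 of them, Hspa1a was below 0 in 13 and Hspa1b in 9 of them. The clusters of a tissue share 1 pair of libraries and are not replicates. Longer digestion, as read by immediate-early genes, is argued against by their median of −0.31 (−0.34 to −0.20), with Jun, Junb and Ier2 below 0 in all 14 clusters, though Zfp36 was above 0 in 7 of them and Dusp1 (0.26) and Fosb (0.10) had medians above 0 in the CNS. Depth per cell as the only cause is argued against, since Bat3cKO cells were shallower in 5 of the 14 clusters and deeper in 4, by intervals of their median UMIs, and the genes had 1 direction in all. The median ratio of the 10 leading genes was 0.54 (0.48 to 0.61) in thinned cells and 0.59 (0.50 to 0.62) in all. Of these genes Ahsa1, Fkbp4, H2-Q7, Cacybp and St13 lie outside the families taken by symbol. All 10 were picked on the same counts, and thinning leaves expected ratios as they were. The bound written beforehand on that value would thus be met either way and decides nothing. A temperature difference in handling stays open, because Cirbp, also cold-induced, had a median of −0.20 with an interval from −0.43 to 0.0021. The genotype stays open as well and was not tested, so handling and genotype cannot be told apart here.

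Genes with the same direction in every cluster compared may also reflect DNA around Bag6 that differs between the genotypes, and 2 of the 36 leading ones, H2-Q7 and H2-Q6, lay within 5 Mb of Bag6 (5.56%, 0.680 to 18.7), against 1.71% of all genes compared. The bound written for this test would have excluded that explanation, wrongly, since with 36 genes the interval holds both the share of all genes and a large excess. Genotype labels exchanged within 1 tissue would put the excess among genes of opposite direction, where the share was 6.90% (2 of 29, 0.846 to 22.8), H2-Q4 and H2-D1. Both stay open, with counts too few to decide and paralogs whose reads are hard to divide. The window of 5 Mb was set after a first look, and the genotype itself was not tested.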

How the results depend on the processing

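The alternative without the naive-type and Klre1 clusters was chosen after the result was seen, as was the split of classes into parts given with their values in the report, and all others were set before the data were examined. No test was run, paired or not, and with 1 library per group no replicate could be left out. Of 49 named gene ratios and 9 list medians past the 1.5-fold size rule, all kept their direction in every setting but the same cluster mix (46 genes and 7 lists) and the one without naive-type and Klre1 clusters (48 genes and 9 lists). Past the size rule were 35 genes and 0 lists with the same cluster mix, 45 and 2 without those clusters, and otherwise at least 48 genes and 7 lists. Each alternative fixed beforehand was run. Of the marker shares 19 moved and 9 did not without thinning, and 18 moved and 10 did not with at least 2 UMIs asked for, as both change detection by construction. Depth limits the rarest transcripts, such as Csf2, Il10 and Havcr2.

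With the same cluster mix, list medians in the CNS were −0.21 for Treg, 0.34 for naive and 0.21 for cytotoxic genes. The sign turned for Th17 (0.40) and Th2 genes (0.18) and for Dapl1 (−0.019), Foxp3 (0.013) and Il17a (0.40). It also turned for the Th1 (−0.22), coinhibitory (0.26), unfolded protein response (0.092) and apoptosis lists (0.029). In dLN the list median was 0.30 for Th17, and the sign turned for Treg (−0.022), cytotoxic (0.072) and cell cycle genes (−0.049). Homing (−0.047), Th1 (−0.038), encephalitogenic (−0.032), TCR-induced (−0.12) and glycolysis genes (−0.11) turned there too. This setting removes differences in cluster shares by construction and leaves out clusters with under 20 cells in a library (92.0% of CNS Bat3cKO cells are kept), so ratios that it takes to near 0 may come from either. Differences of mix inside a cluster stay, as in the CNS Th17-like class, so ratios that it keeps or turns may still hold mix.

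Without the naive-type and Klre1 clusters, the CNS differences in share were −8.62 points for Treg-like and −20.4 for Th17-like cells, with list medians of −0.54 for Treg, −0.13 for Th17 and 0.50 for naive genes. In dLN the Treg-like share turned to −0.206 points, within counting error, Foxp3 to −0.0083 and the Treg list to −0.083, and the medians were 0.44 for Th17, −0.26 for naive and −0.33 for cytotoxic genes. The dLN medians of Th1, coinhibitory, encephalitogenic, TCR-induced, glycolysis and apoptosis genes turned as well, as did the CNS coinhibitory median. Fewer cells enter by construction.

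At resolution 2 the CNS Th17-like difference was −5.56 points, and in dLN those of Treg-like, naive T-like and CD8 T-like cells were 5.36, 0.740 and −6.92 points, the naive one with its sign turned. With each tissue clustered on its own, CNS differences were −3.15 for Th17-like, 22.4 for naive T-like and 8.63 for CD8 T-like cells, and dLN ones 0.900 for Th17-like and −7.77 for CD8 T-like cells. For Th17-like cells of the CNS, part of the cells took another class's name. With that, Th17-like cells per Treg-like cell, as log2 of Bat3cKO over control, turned from −0.28 (−0.55 to −0.016) to 0.50 at resolution 2 and 0.75 with the CNS clustered on its own. The other cell filters, no doublet removal, resolution 0.5 and 50 principal components gave −0.26 to −0.22, with intervals that included 0. The cause of the other shifts was not tested.

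The CNS cytotoxic median was 1.18 with TMM, 1.17 with median-of-ratios factors, 1.15 in the Cd3-positive gate, 1.32 in thinned cells, 1.35 without a low filter and 1.43 with one of 50 CPM. The dLN Treg median was 0.39 with TMM, 0.38 with median-of-ratios factors and 0.40 without ribosomal and mitochondrial genes in the total. The CNS Treg median was −1.01 in thinned cells, and the CNS naive median 0.74 in all cells and 0.73 without a low filter. The dLN Th17 median was 1.13 without a low filter and 0.12 with one of 50 CPM, and the dLN cytotoxic median −0.063 and −0.28, and 0.00036 with equal weight per cell, where its sign turned. Other low filters admit other members by construction. For the other settings the cause was not tested.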

Other observations

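Some genes had opposite ratios in the tissues in each of the 7 CNS and 7 dLN clusters compared, a choice of genes made after their values were seen. Zfp36l2, an RNA-decay factor gene, had median log2 ratios of 1.60 in CNS and −1.41 in dLN clusters, Rpia, of the pentose phosphate pathway, 1.61 and −2.57, and the signalling kinase gene Map3k1 0.70 and −0.88. The reverse was seen for Alyref (−0.79 and 1.55), Taf10 (−0.58 and 1.02), Grb2 (−0.68 and 1.03) and the G protein gene Gnai2 (−0.47 and 0.54). These differences between tissues were not tested, and the clusters of a tissue share the same pair of libraries.

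The non-T cells of the CNS libraries, 33 in the control and 24 in Bat3cKO, carried different marker genes. In the control, the antigen presentation genes Cd74 and H2-Ab1 stood at 13175 and 4471 CPM and Itgax, which encodes CD11c, had 28 UMIs. In Bat3cKO, Cd74 and H2-Ab1 stood at 979 and 169 CPM and Itgax had 0 UMIs, while the fibroblast and meningeal genes Ptgds and Dcn stood at 3985 and 2139 CPM, against 30.6 CPM and 0 (up to 10.2 CPM allowed by 3 counts) in the control. Apoe stood at 15084 CPM in control and 7080 CPM in Bat3cKO cells. Lyz2 was seen in 2.56% of control and 0.572% of Bat3cKO T cells of the CNS. In dLN, the 52 Bat3cKO cells with Il17a lay mostly in the cycling cluster (22 cells) and in an unnamed cluster led by Ramp3 and Tox2 (17 cells).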
